A study of Homo sapiens with 15 samples.

How the data were processed

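RNA from 15 samples of CD14+ monocytes was analysed, 5 donors in each of 3 groups (Unstim, and LPS and IC for 18 h). Per the labels, RNA was extracted with RNeasy columns, libraries were made with the SMART-seq v4 kit, and 50 bp single-end reads were sequenced on an Illumina HiSeq instrument, with 30000000 reads planned per sample. Per the submitters' processing notes, reads were aligned with GSNAP to GRCh38, and the GSNAP version, the gene annotation, the handling of strand and any filters are not given in the sources used here. The kit does not mark the strand of a transcript, so antisense and overlapping genes cannot be told apart by strand.

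The deposited files hold 30727 gene IDs per library in 2 units. Per the file headers, the count is the number of reads that align uniquely to a gene model, as raw counts without normalization. Per the file headers, the other value is an RPKM adjusted by a size factor by the authors, and it was used only to check that it is 0 exactly where the count is 0, which had 0 exceptions. Gene IDs were matched to symbols and positions with the RefSeq gene table of GRCh38.p14, which matched 27814 IDs. The 2913 IDs without a match held 0.416 to 0.63% of the counts and were left out. Genes on the Y chromosome, XIST and TSIX were removed before any fit. HLA-B, HLA-DPA1, HLA-DPB1, HLA-DRA, HLA-E and NDUFA4 had no entry under their symbol and were not analysed here. Positions printed are those of the whole gene in that table.

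The depth used was 23033337 to 34539741 counts per library, with 17885 to 19060 genes having a count. Genes were kept by edgeR's filterByExpr with default settings, which left 14742. Counts were scaled by TMM, and edgeR 4.0.16 (R 4.3.3) fitted a quasi-likelihood model with 1 mean per group over all 15 libraries. The contrasts were IC against Unstim, LPS against Unstim and IC against LPS. P-values were adjusted by Benjamini-Hochberg over the 14742 genes of a contrast, and a gene was called at an adjusted p below 0.05. The common biological coefficient of variation was 0.314, and 0.176 with the donor as a block. SEs of log2 fold changes were derived from the quasi-likelihood F statistic. Levels are TMM-scaled CPM. A gene with no counts in a group is given as a lower bound against 3 counts over the group.

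The 41 gene lists, among them markers of 9 other cell types and 2 signs of RNA quality, were fixed before the data were examined. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 41 lists of a contrast. List members were also counted with p adjusted over the list alone. Summed markers were compared as log2 of summed CPM plus 1 by exact permutation of the 10 libraries, adjusted over 33 tests.

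Genes were named by a rule fixed in advance. The rule took the 8 genes with the largest fold change in each direction among called genes with a mean of at least 10 CPM in either group and the same direction in 5 of 5 donors, without pseudogenes and unnamed loci. It added up to 2 members per list and direction with at least 1 CPM, and the most abundant member of each marker list. From these, genes were picked for the text, and genes outside the rule are named as such. Pearson's r and the covariance of the responses were computed over all tested genes. They were compared with 20 simulated sets of unchanged groups and with 20 splits of the Unstim libraries between the contrasts.

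The numbers in the labels mark the donors. As a check of pairing, deviations of log2 levels from the group mean were correlated over 12696 genes, and in each contrast 5 of 5 libraries correlated best with the library of their own number. Same-number r was 0.222 to 0.66 for IC and Unstim, 0.459 to 0.623 for LPS and Unstim and 0.379 to 0.847 for IC and LPS. Within each group no library was a copy of another, and libraries of different groups were not compared in this way. A fit with the donor as a block was set beforehand as a comparison and was not the fit used for the results. SEs, p-values and counts therefore ignore the pairing unless the block is named. With the block 8808, 7578 and 6141 genes were called, against 6907, 5979 and 4213 without it. A gene or list member that did not pass may thus pass when donors are paired.

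The steps were tested on simulated data with 14598 genes, no change in LPS and 200 genes changed in IC. In IC against Unstim, 22 of 67 genes (32.8%) changed 1.5-fold, 47 of 67 (70.1%) changed 2-fold and 63 of 66 (95.5%) changed 4-fold were called. Of 14398 unchanged genes 4 were called, and 0 of 14598 in LPS against Unstim. In IC against LPS 16, 46 and 63 changed genes and 11 unchanged genes were called. Of 20 simulated lists of 20 genes, the changed list and none of the other 19 were called. In this simulation a 1.5-fold change in a gene was therefore mostly missed. It held only 200 changed genes, drawn from the more highly expressed genes, and was fitted without the donor block. Each gene was simulated independently, whereas genes of a real list can move together. The interferon-stimulated genes, for example, had an estimated correlation of 0.893 in IC against Unstim. The simulated lists therefore do not show how often camera calls unchanged lists of correlated genes. The real contrasts called far more genes, which loosens the adjusted threshold, so these shares may not hold for them.

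The alternatives run were the donor block, DESeq2 1.42.0, limma-voom, RLE, upper quartile and library size scaling, other filters on low counts, fits of 2 groups only, a threshold of 0.01 and leaving out each library in turn. For lists they were an estimated correlation, fry and permutation of list means. For summed markers they included a pseudocount of 0.1 CPM and sign flips within donors. IDs without a symbol, and the fit without the 3 libraries of number 5, were added later. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.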

Results

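CD14+ monocytes, blood cells that sense microbial products and antibody-coated particles, were purified from mononuclear cells of 5 donors, and their RNA was sequenced. Cells of each donor went into 3 groups of 5 libraries. Unstim cells had no stimulus, LPS cells had lipopolysaccharide, a bacterial cell wall component sensed through TLR4, for 18 h, and IC cells had immune complexes fixed to the plate, which engage Fc receptors, for 18 h. Whether and for how long the Unstim cells were cultured is not given in the sources used here, so every difference from Unstim may also hold an effect of culture. The labels give the aim as describing how immune complexes activate monocytes, in the setting of systemic sclerosis. The labels name the vehicle DMSO for the LPS and IC groups and no vehicle for Unstim, so vehicle and stimulation went together in every comparison with Unstim. The counts used came to 23033337 to 34539741 per library, with means of 30200000 ± 2890000 (SD, n = 5) in Unstim, 29400000 ± 3980000 in LPS and 31100000 ± 2300000 in IC. The 10 genes with the most counts took 8.8 ± 0.43% of the counts in Unstim, 13.54 ± 1.99% in LPS and 16.15 ± 0.78% in IC. Levels below are TMM-scaled CPM as mean ± SD over the 5 libraries of a group, and log2 fold changes are given ± SE. Counts of genes and of list members rest on edgeR's quasi-likelihood test at an adjusted p below 0.05 over all 14742 genes tested. That test does not pair the donors, and pairing them called more genes in each comparison. For a gene list, the count adjusted over the list alone is added where it differs.

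The comparison of IC with Unstim asked what immune complexes change in monocytes. IC raised PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, from 151 ± 86.9 to 14300 ± 2870 CPM. TNFSF15, a cytokine of the TNF family, rose from 3.03 ± 0.53 to 991 ± 308 CPM, and CXCL1, a chemokine that attracts neutrophils, from 354 ± 126 to 5370 ± 1170 CPM. CTSD, the lysosomal protease cathepsin D, fell from 5070 ± 1210 to 455 ± 89.2 CPM, and FN1, the matrix protein fibronectin, from 272 ± 68.5 to 1.79 ± 1.6 CPM. Each of the 38 interferon-stimulated genes tested was lower in IC, with a median log2 fold change of -3.25. Platelet marker genes were also higher in the IC libraries (PPBP 550 ± 183 against 133 ± 49.8 CPM), as were 10 of the 13 mitochondrially encoded mRNAs.

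Of the 14742 genes tested, 3580 were higher and 3327 lower in IC than in Unstim, and 2897 of these differed at least 2-fold. Of the called genes 51.8% were higher. With scaling to library size only, the median log2 fold change of all genes shifted to -0.14 and 2555 genes were higher and 4181 lower, which made 37.9% higher. The share was 47.2% without LPS replicate 1, a library outside this contrast, and 51.2% with the donor block.

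Among the genes with the largest rises, MMP10 (chromosome 11, 102770502 to 102780628) and MMP1 (chromosome 11, 102789919 to 102798160), enzymes that cut matrix proteins, rose from 0.0969 ± 0.045 to 91.9 ± 18.4 CPM and from 1.18 ± 0.534 to 624 ± 237 CPM. Their log2 fold changes were 9.81 ± 0.61 (adjusted p = 3.95e-08, edgeR) and 9.04 ± 0.72 (adjusted p = 2.74e-07, edgeR), and each was higher in 5 of 5 donors. FLT1, a receptor for vascular endothelial growth factor, rose from 1.81 ± 1.24 to 680 ± 95.7 CPM. F3, tissue factor, which starts blood clotting, rose from 2.62 ± 1.73 to 321 ± 68.8 CPM, and TFPI2 (chromosome 7, 93885396 to 93890753), a protease inhibitor, from 5.51 ± 2.59 to 872 ± 347 CPM. SERPINB4 had no counts in Unstim and 24.3 ± 16.8 CPM in IC, at least 1310-fold higher against 3 counts over the Unstim group. Reads of SERPINB4 and its near-identical neighbour SERPINB3 are hard to tell apart, and a pseudogene overlaps MMP1, so these values are uncertain.

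Among the genes with the largest falls, CCL8 (chromosome 17, 34319435 to 34321402), a chemokine for monocytes, fell from 109 ± 141 to 0.137 ± 0.139 CPM (log2 fold change -9.53 ± 1.47, adjusted p = 0.000103, edgeR), in 5 of 5 donors, and this call was lost with limma-voom (adjusted p = 0.0635). SLCO2B1, an organic anion transporter, fell from 92.4 ± 59.3 to 0.13 ± 0.147 CPM, and RNASE1, a secreted ribonuclease, from 564 ± 588 to 1.36 ± 1.11 CPM. FUCA1, a lysosomal fucosidase, fell from 630 ± 398 to 5.54 ± 1.54 CPM and GPNMB, a membrane glycoprotein of macrophages, from 956 ± 364 to 11.9 ± 10 CPM.

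Of 41 gene lists fixed before the data were examined, 17 passed camera's competitive test at the preset correlation of 0.01 in this comparison, 11 with higher and 6 with lower members. With a correlation estimated per list, 5 held: proinflammatory cytokines (adjusted p = 0.0372 with an estimated correlation), neutrophil-attracting CXC chemokines (0.0372), scavenger and phagocytic receptors (0.0441), lipid efflux and LXR targets (0.0441) and the lysosome (0.0441). With the donor block as well as an estimated correlation, 0 lists held, so these 5 calls were lost too. An exact permutation of list means called 27 lists, 16 of them among the 17, and left out MHC class I presentation (adjusted p = 0.105). Of the 11 it added, those with a higher list mean in IC were matrix proteases, erythroid and plasmacytoid dendritic cell markers (adjusted p = 0.0142 each) and cytosolic ribosomal proteins (0.0251). Those with a lower list mean were complement, Fc receptors, Toll-like receptors, alternative activation, classical monocyte genes and neutrophil and conventional dendritic cell markers (0.0142 each). Splits of the same libraries that do not follow the groups also passed many lists with camera, though each such split keeps part of the group difference.

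Among 19 proinflammatory cytokines, 14 rose and 2 fell, with a median log2 fold change of 4.50 (camera adjusted p = 1.16e-16). CSF3, the growth factor of neutrophils, rose from 9.44 ± 4.99 to 903 ± 182 CPM, whereas IL18 fell from 22.8 ± 3.26 to 1.3 ± 0.342 CPM. All 6 CXC chemokines that attract neutrophils rose, with a median of 3.77 (adjusted p = 5.44e-13). CXCL6 rose from 3.08 ± 3.1 to 82.7 ± 38 CPM. CC chemokines went both ways, 7 up and 6 down of 14 (median 1.46, mean 0.51, adjusted p = 0.014). CCL20, which attracts CCR6-bearing lymphocytes, rose from 41.1 ± 27.7 to 1650 ± 314 CPM, while CCL7 fell from 188 ± 170 to 12.1 ± 9.71 CPM. The CC chemokine call was lost with an estimated correlation (adjusted p = 0.211 with an estimated correlation), with the donor block (adjusted p = 0.21) and without the 3 libraries of number 5 (adjusted p = 0.0654).

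Of 20 genes of the NF-kB pathway and its feedback, 17 rose and 1 fell (median 1.04, adjusted p = 9.2e-12, and adjusted p = 0.182 with an estimated correlation). TNIP3 rose from 30.6 ± 13.1 to 480 ± 107 CPM and TNFAIP6, an anti-inflammatory secreted protein, from 79.2 ± 21.1 to 477 ± 92 CPM. Of 14 genes of costimulation and dendritic maturation, 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 0.89, adjusted p = 0.000509, and adjusted p = 0.182 with an estimated correlation). CD274, the checkpoint ligand PD-L1, rose from 46.1 ± 7.8 to 513 ± 129 CPM, and CD86, a costimulatory ligand, fell from 317 ± 72.3 to 143 ± 49.1 CPM. Anti-inflammatory mediators had 8 higher and 4 lower of 15 (median 0.49, adjusted p = 0.0433, and adjusted p = 0.479 with an estimated correlation). That call was lost when Unstim replicate 3 or 5 or IC replicate 2 or 3 was left out, with adjusted p of 0.0683, 0.0557, 0.0533 and 0.0743.

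Interferon-stimulated genes fell together. SIGLEC1, a sialic acid-binding receptor of the list, fell from 803 ± 670 to 12.6 ± 14 CPM and IFIT1, an antiviral RNA-binding protein, from 331 ± 298 to 9.87 ± 14 CPM. The list passed camera (adjusted p = 3.57e-09) and the exact permutation (adjusted p = 0.0251), and not with an estimated correlation (adjusted p = 0.479 with an estimated correlation). The large SDs in Unstim show that the level of these genes varied widely between unstimulated libraries. Of 10 tested genes of MHC class II presentation, 7 were lower and none higher, or 9 lower adjusted over the list alone (median -1.25, adjusted p = 0.000142, and adjusted p = 0.161 with an estimated correlation). IFI30, a lysosomal reductase, fell from 4520 ± 893 to 1010 ± 264 CPM and CTSS, a protease of antigen processing, from 1290 ± 301 to 319 ± 29.6 CPM. HLA-DRA, HLA-DPA1, HLA-DPB1, HLA-B and HLA-E were not analysed here.

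Receptors for uptake and genes of the lysosome were lower in IC. Of 15 scavenger and phagocytic receptors, 13 fell and 1 rose (median -2.02, adjusted p = 5.88e-06). MERTK, a receptor for apoptotic cells, fell from 289 ± 68.3 to 10.2 ± 4.09 CPM and STAB1, the scavenger receptor stabilin-1, from 687 ± 251 to 26.3 ± 4.4 CPM, whereas MARCO rose from 14.6 ± 10.2 to 106 ± 51.4 CPM. Of 22 lysosome genes, 18 fell and none rose (median -0.90, adjusted p = 3.15e-13). GAA, the lysosomal glucosidase, fell from 334 ± 34.4 to 66.1 ± 16.6 CPM. Lipid efflux and LXR targets had 10 lower and 1 higher of 14 (median -1.19, adjusted p = 1.36e-07). NR1H3, the lipid-sensing receptor LXR alpha (chromosome 11, 47248300 to 47269033), fell from 222 ± 25.8 to 9.2 ± 2.39 CPM and APOE, a lipid carrier, from 49.8 ± 28.9 to 0.791 ± 0.265 CPM. Of 22 cholesterol biosynthesis genes, 16 rose and none fell (median 0.64, adjusted p = 1.88e-05, and adjusted p = 0.195 with an estimated correlation). SQLE, a rate-limiting enzyme of that pathway, rose from 17 ± 3.29 to 53.6 ± 6.98 CPM and MSMO1 from 7.14 ± 1.28 to 22.1 ± 2.87 CPM.

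Fibrosis-linked growth factors and matrix had 9 higher and 4 lower of 21, or 10 higher adjusted over the list alone and 14 with the donor block (median 1.29, adjusted p = 0.016, and adjusted p = 0.11 with an estimated correlation). SPP1, the secreted protein osteopontin (chromosome 4, 87975714 to 87983411), rose from 44.3 ± 28.3 to 1220 ± 485 CPM and EDN1, the vasoconstrictor endothelin-1, from 0.44 ± 0.108 to 39 ± 40.1 CPM. TGFBI, a matrix protein, fell from 4840 ± 3440 to 125 ± 42.1 CPM. The 22 matrix proteases and plasminogen genes had 11 higher and 9 lower members and did not pass camera as a list (adjusted p = 0.503), though the permutation of list means called it (0.0142), and MMP9 fell from 2960 ± 1050 to 399 ± 115 CPM. Eicosanoid genes had 5 higher and 9 lower of 17, or 10 lower adjusted over the list alone, and did not pass as a list (adjusted p = 0.267), with a median of -0.64 and a mean of 0.19. PTGES, the prostaglandin E synthase, rose from 33 ± 14.2 to 663 ± 237 CPM, while ALOX5 and LTA4H, enzymes of leukotriene synthesis, fell from 267 ± 56.8 to 44.9 ± 10.8 CPM and from 328 ± 203 to 53.8 ± 11.3 CPM. The classical monocyte genes had 4 higher and 6 lower of 14 (median -0.58, adjusted p = 0.053, and adjusted p = 0.313 with an estimated correlation). The list passed with the donor block (adjusted p = 0.0447), with the permutation of list means (0.0142) and with fry (0.000196, and 0.000318 with the block). It also passed without Unstim replicate 1 (0.0309), 2 (0.0475), 3 (0.0298), 4 (0.0483) or 5 (0.029), LPS replicate 1 (0.0483), 2 (0.0472) or 3 (0.039) or IC replicate 3 (0.0474). CCR2, the receptor for CCL2, fell from 52.1 ± 25 to 0.965 ± 0.594 CPM and CSF3R, the receptor for CSF3, from 205 ± 57 to 14.3 ± 1.29 CPM. FCGR3A, the Fc receptor CD16, fell from 888 ± 217 to 111 ± 58.6 CPM, and reads of its near-identical copy FCGR3B may be split between the genes.

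The 12 platelet markers had 11 higher and none lower (median 1.68, adjusted p = 0.000138, and adjusted p = 0.244 with an estimated correlation). The 13 mitochondrially encoded mRNAs had 10 higher and none lower (median 0.64, adjusted p = 0.000504, and adjusted p = 0.479 with an estimated correlation). These lists stood beside every list above that rose in IC.

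**Figure D1:**
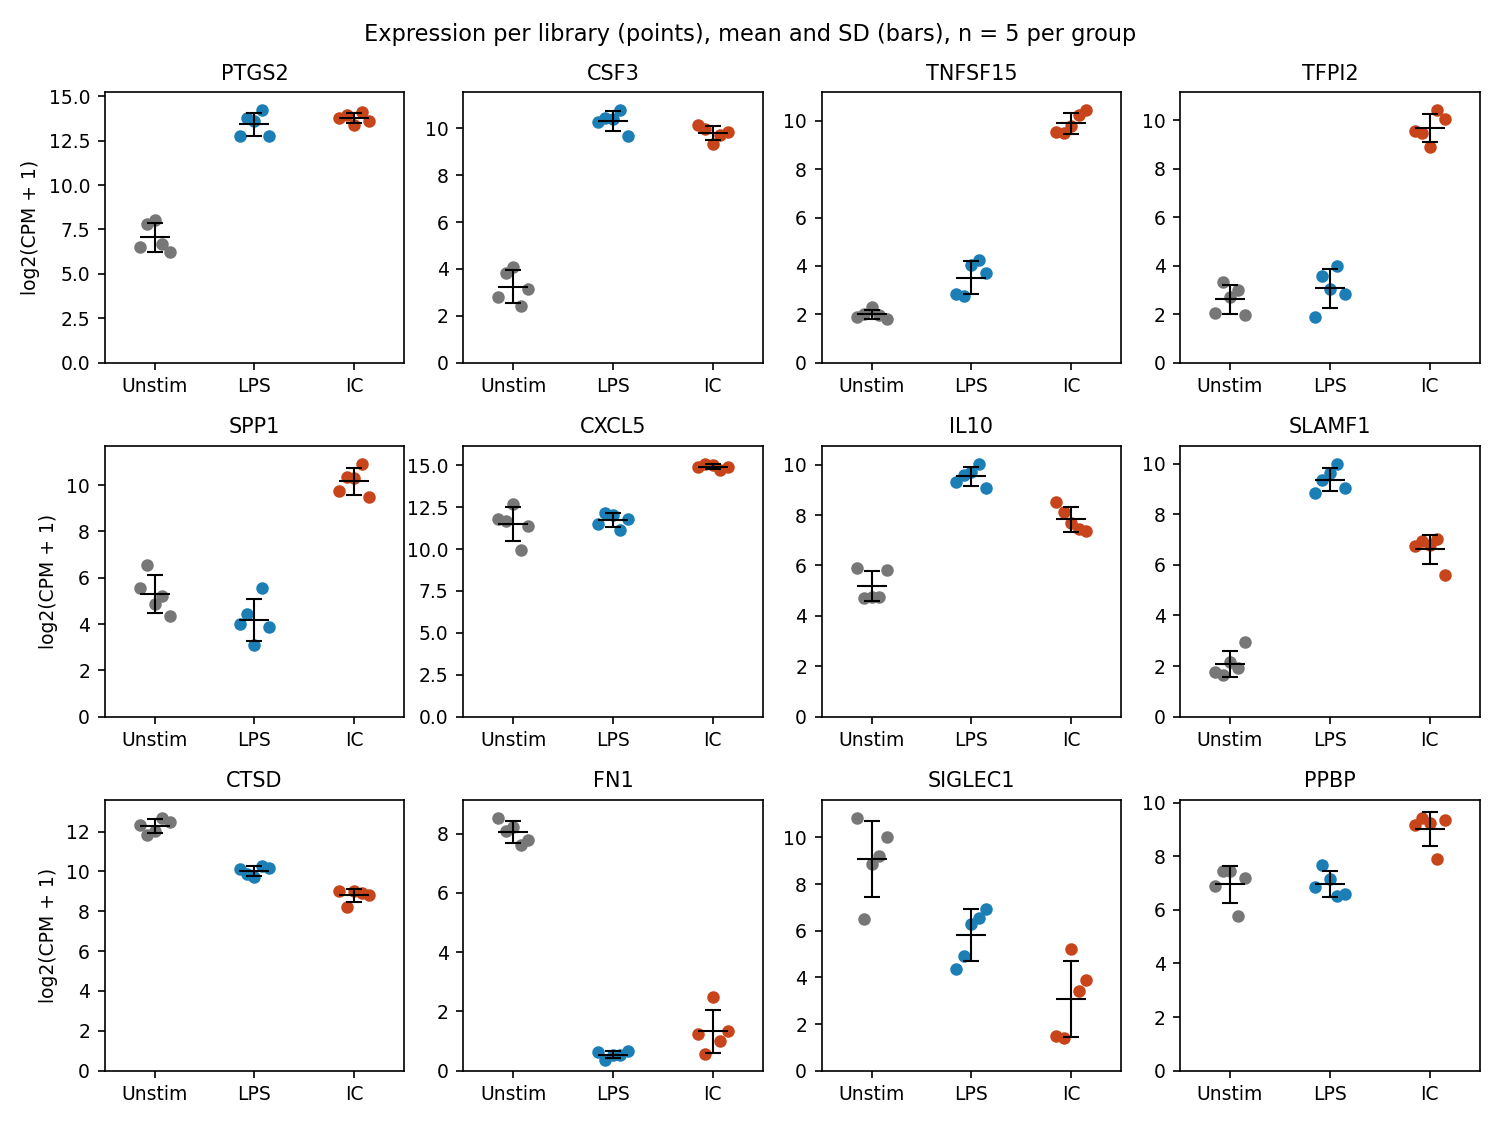
Expression of 12 genes in each library, with log2(CPM + 1) on the vertical axis from 0 and the groups Unstim (grey), LPS (blue) and IC (orange) on the horizontal axis (points, libraries; bars, mean and SD of 5). TNFSF15 lay between 9.49 and 10.46 in IC and between 2.75 and 4.24 in LPS, and SLAMF1 between 5.59 and 7.01 in IC and between 8.83 and 10 in LPS.

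The comparison of LPS with Unstim asked what a bacterial stimulus changes in the same cells. LPS raised PTGS2 from 151 ± 86.9 to 12000 ± 5250 CPM and CSF3 from 9.44 ± 4.99 to 1310 ± 348 CPM. SLAMF1, a receptor of activated lymphoid and myeloid cells (chromosome 1, 160608106 to 160647044), rose from 3.5 ± 1.87 to 687 ± 225 CPM, and IL10, an anti-inflammatory cytokine (chromosome 1, 206767602 to 206772494), from 38.1 ± 16.9 to 767 ± 199 CPM. FPR3, a formyl peptide receptor, fell from 1250 ± 191 to 6.39 ± 4.86 CPM, and FN1 from 272 ± 68.5 to 0.455 ± 0.115 CPM. Of the 38 interferon-stimulated genes 33 fell and none rose.

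Of the 14742 genes, 2874 were higher and 3105 lower in LPS than in Unstim, and 2662 differed at least 2-fold. Of the called genes 48.1% were higher. With library size only, the median of all genes shifted to -0.19 and 2013 genes were higher and 4254 lower, which made 32.1% higher.

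ADAMTS4, a protease that cuts aggrecan, had 3 counts over the Unstim group and 95.6 ± 40.7 CPM in LPS, a ratio of 5180 with a 95% counting interval of 1770 to 25100. SERPINB4 was at 83.8 ± 46.8 CPM, at least 4540-fold higher against 3 counts over the Unstim group. MMP1 rose from 1.18 ± 0.534 to 851 ± 743 CPM (log2 fold change 9.49 ± 0.73, adjusted p = 1.7e-07, edgeR), in 5 of 5 donors. FCAMR, an Fc receptor for IgA and IgM, rose from 0.0431 ± 0.0164 to 25.7 ± 11.5 CPM. RNASE1 fell from 564 ± 588 to 0.71 ± 1.2 CPM, CCL7 from 188 ± 170 to 0.762 ± 1.09 CPM and MSR1, a scavenger receptor, from 65.1 ± 55.7 to 0.593 ± 0.481 CPM. CCL8 fell from 109 ± 141 to 0.19 ± 0.346 CPM (log2 fold change -9.19 ± 1.44, adjusted p = 0.000121, edgeR), and this call was lost with limma-voom (adjusted p = 0.0786). TGFBI fell from 4840 ± 3440 to 59.9 ± 47.9 CPM and STAB1 from 687 ± 251 to 29.3 ± 18.7 CPM.

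In this comparison 15 of the 41 lists passed camera, 8 with higher and 7 with lower members, and an exact permutation of list means called 22, 11 of them among the 15. The permutation left out CC chemokines (adjusted p = 0.356), interferon-stimulated genes (0.052), glycolysis (0.0697) and cytosolic ribosomal proteins (0.0786). With a higher list mean in LPS it added inflammasome, matrix proteases, cholesterol biosynthesis and the unfolded protein response (adjusted p = 0.0163 each) and eicosanoid genes (0.0444). With a lower list mean it added Fc receptors, fibrosis-linked genes, alternative activation, classical monocyte genes and conventional dendritic cell markers (0.0163 each) and Toll-like receptors (0.0444). For the eicosanoid and fibrosis-linked lists camera had the opposite direction and did not call them. None of the 15 lists that camera called held with an estimated correlation.

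Of 19 proinflammatory cytokines, 13 rose and 2 fell, or 14 and 2 adjusted over the list alone (median 2.62, adjusted p = 5.59e-10, and adjusted p = 0.171 with an estimated correlation). IL23A, a subunit of interleukin-23, rose from 2.23 ± 0.717 to 199 ± 112 CPM and IL18 fell from 22.8 ± 3.26 to 4.31 ± 2.1 CPM. Of 15 anti-inflammatory mediators, 10 rose and 2 fell (median 1.18, adjusted p = 4.39e-05, and adjusted p = 0.201 with an estimated correlation). SOCS1, an inhibitor of cytokine signalling, rose from 9.15 ± 3.25 to 91.6 ± 27.2 CPM. Of 20 NF-kB genes 18 rose and none fell (median 1.37, adjusted p = 2.19e-17, and adjusted p = 0.171 with an estimated correlation), among them TNIP3 from 30.6 ± 13.1 to 663 ± 81 CPM and TNFAIP6 from 79.2 ± 21.1 to 1330 ± 288 CPM. Of the 6 CXC chemokines 5 rose (median 2.45, adjusted p = 3.56e-06, and adjusted p = 0.194 with an estimated correlation), CXCL1 to 2990 ± 366 and CXCL6 to 33.8 ± 17.5 CPM. CC chemokines had 7 higher and 4 lower of 14, or 8 and 4 adjusted over the list alone (median 1.92, mean 0.10, adjusted p = 0.00964, and adjusted p = 0.253 with an estimated correlation). CCL19, which guides dendritic and T cells, rose from 4.68 ± 1.83 to 153 ± 18.3 CPM and CCL3 from 130 ± 35.7 to 2870 ± 1470 CPM. The CC chemokine call was lost with the donor block (adjusted p = 0.0587) and without the 3 libraries of number 5 (adjusted p = 0.152).

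Costimulation and dendritic maturation had 9 higher and 2 lower of 14 (median 1.27, adjusted p = 0.00147, and adjusted p = 0.261 with an estimated correlation). CD274 rose from 46.1 ± 7.8 to 542 ± 124 CPM and CD86 fell from 317 ± 72.3 to 47.9 ± 3.1 CPM. Of 9 tested metallothionein list genes 7 rose, or 8 adjusted over the list alone (median 2.50, adjusted p = 0.00124, and adjusted p = 0.495 with an estimated correlation). MT1M rose from 1.64 ± 1.77 to 12.9 ± 7.61 CPM and MT1G from 2.2 ± 2.2 to 15.3 ± 10.7 CPM, and reads are uncertain among the similar MT1 genes.

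Interferon-stimulated genes had 33 lower of 38, or 34 adjusted over the list alone (median -2.44, adjusted p = 1.97e-05, and adjusted p = 0.714 with an estimated correlation). CXCL10, an interferon-induced chemokine for T cells, fell from 16.5 ± 19.4 to 0.246 ± 0.212 CPM. MHC class II presentation had 8 lower of 10 (median -1.42, adjusted p = 8.94e-05, and adjusted p = 0.194 with an estimated correlation), with HLA-DMA down from 44.4 ± 14.5 to 9.1 ± 2.35 CPM and HLA-DMB from 18.3 ± 8.6 to 3.8 ± 1.89 CPM. Scavenger and phagocytic receptors had 12 lower and 1 higher of 15, or 2 higher adjusted over the list alone (median -2.27, adjusted p = 0.000114, and adjusted p = 0.171 with an estimated correlation), with AXL down from 13.1 ± 10.8 to 0.389 ± 0.226 CPM. The lysosome had 12 lower and 2 higher of 22, or 3 higher adjusted over the list alone and 4 with the donor block (median -0.66, adjusted p = 0.000636, and adjusted p = 0.443 with an estimated correlation). CTSD fell from 5070 ± 1210 to 1060 ± 171 CPM, while CTSH, another lysosomal protease, rose from 330 ± 92.8 to 920 ± 188 CPM. Lipid efflux and LXR targets had 6 lower and 2 higher of 14, or 3 higher adjusted over the list alone and 4 with the donor block (median -0.31, adjusted p = 0.0412, and adjusted p = 0.495 with an estimated correlation). That call was lost with the donor block (adjusted p = 0.0528), without the 3 libraries of number 5 (0.129), and when LPS replicate 3 or 5 or IC replicate 3 or 5 was left out (0.0604, 0.0967, 0.0505 and 0.0632).

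Of 32 cytosolic ribosomal protein genes 16 fell and none rose, or 18 fell adjusted over the list alone (median -0.32, adjusted p = 0.00964, and adjusted p = 0.83 with an estimated correlation), and the call was lost without the 3 libraries of number 5 (adjusted p = 0.0887). RPL27A fell from 56.4 ± 5.78 to 37.8 ± 4.39 CPM and RPS6 from 217 ± 44.7 to 151 ± 26.2 CPM, and processed pseudogenes can share reads with such genes. PTGS1, the constitutive cyclooxygenase, fell from 200 ± 25.6 to 30.2 ± 4.37 CPM, and FCGR3A from 888 ± 217 to 69.9 ± 16.2 CPM. The eicosanoid list had 5 higher and 8 lower of 17 and did not pass camera (adjusted p = 0.598, and 0.0444 by permutation of list means), with a median of -0.35 and a mean of 0.31. Platelet markers had 1 higher of 12 (median 0.14, and -0.04 with library size only; PPBP 129 ± 46.4 CPM), and none of the 13 mitochondrially encoded mRNAs passed the test (median -0.05). Beside the lists above, neutrophil markers had 8 lower of 12 (median -1.55, adjusted p = 0.00661, and adjusted p = 0.261 with an estimated correlation). NK cell markers had 1 higher of 10, or 6 with the donor block, and did not pass as a list (median 1.10, adjusted p = 0.389).

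The responses to IC and LPS were compared over the 14742 genes. Pearson's r between their log2 fold changes against Unstim was 0.801 across genes, which are not independent replicates. Both comparisons use the same 5 Unstim libraries, and 20 simulated pairs of unchanged groups against such controls gave a median r of 0.498 (0.48 to 0.544). The covariance was 1.067, against 0.0536 in the simulation, a difference of 1.013. In both comparisons 1966 genes were higher and 2104 lower, while 102 went opposite ways. Independent lists of these sizes would share 698 and 701 genes. The simulated unchanged groups shared 0, but almost no gene was called in them, so that 0 was fixed in advance and is no baseline for the overlap. With the Unstim libraries split between the comparisons, r was 0.667, the covariance 1.068, and the shared genes numbered 1301 and 1569 (medians of 20 splits). The simulated sets kept 14318 to 14353 genes, and each split fit kept 15786 genes with 2 or 3 Unstim libraries per comparison. Values of the splits therefore also differ from those above by the genes tested and by power, beside the unshared controls.

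**Figure D2:**
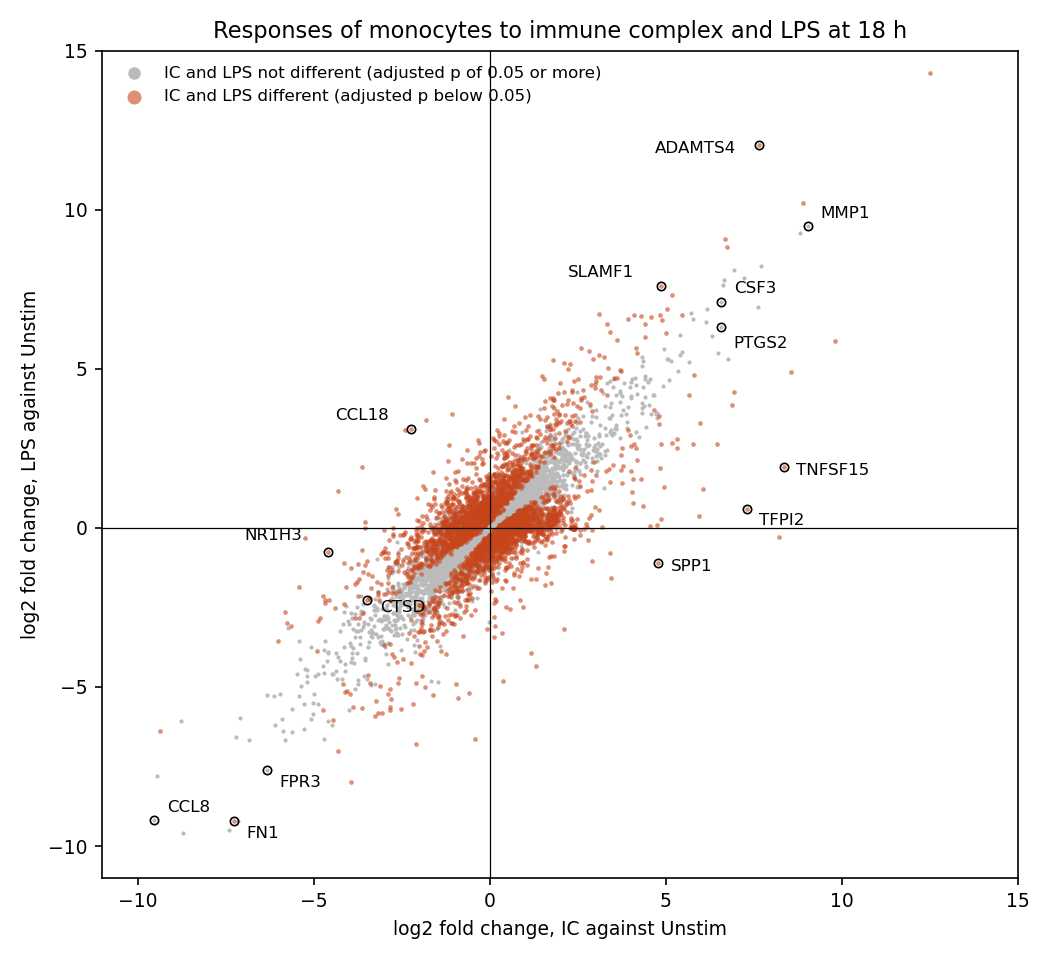
Log2 fold change of each of 14742 genes in LPS against Unstim (vertical axis) and in IC against Unstim (horizontal axis), orange where IC and LPS differed at an adjusted p below 0.05 (edgeR), grey otherwise, circled where named. MMP1 and PTGS2 lie far up and to the right, TFPI2, TNFSF15 and SPP1 far to the right, and CCL18 lies above 0 in LPS and below 0 in IC.

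The direct comparison of IC with LPS asked where the stimuli differ. IC held far more TFPI2 (872 ± 347 against 8.36 ± 4.63 CPM), TNFSF15 (991 ± 308 against 11.4 ± 5.43 CPM) and SPP1 (1220 ± 485 against 20.7 ± 15.1 CPM) than LPS. LPS held more IL10 (767 ± 199 against 238 ± 85.1 CPM), SLAMF1 (687 ± 225 against 103 ± 32.3 CPM) and NR1H3 (131 ± 33.8 against 9.2 ± 2.39 CPM). CXCL5, a chemokine for neutrophils, stood at 31000 ± 3080 CPM in IC and 3500 ± 961 CPM in LPS. Platelet markers and mitochondrially encoded mRNAs were higher in IC, and cytosolic ribosomal protein genes were lower in LPS.

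Of the 14742 genes, 2270 were higher and 1943 lower in IC than in LPS, and 1391 differed at least 2-fold. Without LPS replicate 2, 1499 genes were higher and 1731 lower, so the excess of higher genes reversed. Other libraries left out gave similar counts (1551 and 1751 without IC replicate 1, 1553 and 1749 without LPS replicate 1 and 1590 and 1768 without LPS replicate 3). The excess also reversed with DESeq2 (2322 and 2372) and held with the donor block (3262 and 2879). With the stricter threshold of 0.01, 1211 were higher and 1077 lower.

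Log2 fold changes were 6.70 ± 0.52 for TFPI2 (adjusted p = 1.94e-06, edgeR), 6.44 ± 0.37 for TNFSF15 (adjusted p = 2.15e-07, edgeR) and 5.89 ± 0.58 for SPP1 (adjusted p = 1.29e-05, edgeR), each in 5 of 5 donors. GREM1, an inhibitor of bone morphogenetic proteins, was at 44.1 ± 29.2 CPM in IC and 0.868 ± 0.464 CPM in LPS. EGR2, a transcription factor, was at 38.4 ± 20.1 and 1.06 ± 0.842 CPM, and CSF2, the growth factor GM-CSF, at 45.5 ± 38.9 and 1.58 ± 1.19 CPM. In Unstim GREM1 stood at 17.6 ± 13.6 CPM and EGR2 at 29.5 ± 9.42 CPM, so the LPS level of both lay below that of Unstim. Lower in IC were the chemokines CCL18 (0.666 ± 0.28 against 27.9 ± 14.7 CPM) and CCL23 (1.27 ± 0.648 against 46.8 ± 20.9 CPM). ENPP2, the enzyme autotaxin, was at 3.2 ± 1.29 CPM in IC and 80.6 ± 60 CPM in LPS, ADAMTS4 at 4.55 ± 2.03 and 95.6 ± 40.7 CPM, and ADAMDEC1 at 29.2 ± 16.5 and 385 ± 133 CPM. ADAMDEC1 stood at 340 ± 139 CPM in Unstim, near its LPS level. CCL7 was higher in IC (12.1 ± 9.71 against 0.762 ± 1.09 CPM, adjusted p = 0.00649, edgeR), a call lost with limma-voom (adjusted p = 0.0694).

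In this comparison 18 of 41 lists passed camera, 8 with higher and 10 with lower members, and none held with an estimated correlation, while the exact permutation of list means called 14, 12 of them among the 18. The permutation left out anti-inflammatory mediators (adjusted p = 0.0765), interferon-stimulated genes (0.312), NF-kB genes (0.148), Toll-like receptors and adaptors (0.061), classical monocyte genes (0.061) and oxidative phosphorylation (0.124). It added the unfolded protein response (0.0466) and neutrophil markers (0.025), both with a higher list mean in IC.

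Of 19 proinflammatory cytokines 7 were higher and 3 lower in IC (adjusted p = 0.0013, and adjusted p = 0.359 with an estimated correlation), with a median of -0.08 and a mean of 1.14. TNF and IL1B were outside the rule for named genes and were chosen after their values were seen. TNF was at 296 ± 114 CPM in IC and 39.5 ± 8 CPM in LPS (log2 fold change 2.91 ± 0.24, adjusted p = 4.26e-06, edgeR), and IL1B at 35100 ± 3420 and 37000 ± 9120 CPM (adjusted p = 0.896, edgeR). Neutrophil-attracting CXC chemokines had 4 of 6 higher in IC, or 5 adjusted over the list alone (median 1.27, adjusted p = 6.28e-05, and adjusted p = 0.241 with an estimated correlation). CXCL3 was at 5080 ± 658 CPM in IC and 1420 ± 393 CPM in LPS, and its reads are uncertain against CXCL1 and CXCL2.

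Anti-inflammatory mediators had 9 lower and 2 higher of 15 in IC, or 10 lower adjusted over the list alone (median -0.65, adjusted p = 0.00276, and adjusted p = 0.322 with an estimated correlation). TGFB1 was higher in IC (260 ± 44 against 117 ± 17.7 CPM), and platelets carry its transcript too. NF-kB genes had 8 lower and 2 higher of 20, or 9 lower adjusted over the list alone (median -0.35, adjusted p = 0.0126, and adjusted p = 0.729 with an estimated correlation), with TNFAIP3, an inhibitor of NF-kB, at 868 ± 132 CPM in IC and 2010 ± 209 CPM in LPS. TNFAIP6 was at 477 ± 92 and 1330 ± 288 CPM. The NF-kB call was lost without LPS replicate 4 (adjusted p = 0.0847) or IC replicate 5 (adjusted p = 0.0784). Inflammasome genes had 5 lower and 1 higher of 10, or 6 lower adjusted over the list alone (median -0.62, adjusted p = 0.0152, and adjusted p = 0.174 with an estimated correlation). NAIP was at 5.61 ± 4.67 CPM in IC and 23.5 ± 12.1 CPM in LPS and CASP5 at 21.8 ± 9.44 and 57.3 ± 20 CPM. In Unstim NAIP stood at 40.9 ± 14.6 CPM and CASP5 at 5.74 ± 3.48 CPM. Complement genes had 4 lower and 1 higher of 17, or 7 lower with the donor block (median -0.68, adjusted p = 0.00586, and adjusted p = 0.174 with an estimated correlation), with CFB, complement factor B, at 24.6 ± 8.03 CPM in IC and 334 ± 72.4 CPM in LPS.

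Fibrosis-linked growth factors and matrix had 7 higher and 1 lower of 21 in IC, or 12 higher with the donor block (median 0.96, adjusted p = 0.000643, and adjusted p = 0.146 with an estimated correlation). Matrix proteases did not pass as a list (5 higher and 8 lower of 22, adjusted p = 0.617). MMP10 was at 91.9 ± 18.4 CPM in IC and 6.07 ± 4.56 CPM in LPS, and TIMP3, a protease inhibitor, at 24.6 ± 15.9 and 207 ± 117 CPM. Scavenger receptors had 3 higher and 4 lower of 15 (adjusted p = 0.57), with a median of 0.06 and a negative direction in camera. CD163, the receptor for haemoglobin complexes, was at 187 ± 109 CPM in IC and 799 ± 195 CPM in LPS, MERTK at 10.2 ± 4.09 and 40.5 ± 18.5 CPM, and MSR1 at 15.2 ± 14.2 and 0.593 ± 0.481 CPM. CD163 stood at 484 ± 273 CPM in Unstim.

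The lysosome had 14 lower and 2 higher of 22 in IC, or 16 lower adjusted over the list alone (median -0.73, adjusted p = 7.62e-08, and adjusted p = 0.174 with an estimated correlation). CTSH was at 339 ± 71.1 CPM in IC and 920 ± 188 CPM in LPS, while LIPA, the lysosomal acid lipase, was higher in IC (19.7 ± 8.3 against 5.96 ± 3.32 CPM). LIPA stood at 14.4 ± 8.16 CPM in Unstim. Lipid efflux and LXR targets had 7 lower and 1 higher of 14 (median -0.68, adjusted p = 1.03e-05, and adjusted p = 0.174 with an estimated correlation). Cholesterol biosynthesis had 12 higher and 1 lower of 22, or 15 higher adjusted over the list alone (median 0.47, adjusted p = 0.00174, and adjusted p = 0.371 with an estimated correlation). INSIG1, a regulator of that pathway, was at 1160 ± 458 CPM in IC and 399 ± 190 CPM in LPS and STARD4 at 56.5 ± 16.8 and 25.1 ± 8.21 CPM, whereas LSS was lower in IC (153 ± 34.2 against 400 ± 48.7 CPM). Metallothioneins had 6 lower of 9 in IC, or 7 adjusted over the list alone (median -1.37, adjusted p = 0.000501, and adjusted p = 0.377 with an estimated correlation). MT1H was at 0.41 ± 0.327 CPM in IC and 4.25 ± 3.47 CPM in LPS, and MT1M at 1.98 ± 1.54 and 12.9 ± 7.61 CPM, a call that was lost without the 3 libraries of number 5 (adjusted p = 0.0552).

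Cytosolic ribosomal protein genes had 30 of 32 higher in IC, or 31 adjusted over the list alone (median 0.52, adjusted p = 3.74e-11, and adjusted p = 0.371 with an estimated correlation). RPL10A was at 46.3 ± 6.83 CPM in IC and 24.9 ± 6.1 CPM in LPS. Costimulation genes had 3 higher and 2 lower of 14 and did not pass (adjusted p = 0.95), with a median of -0.24 and a mean of 0.04. CD86 was higher in IC than in LPS (143 ± 49.1 against 47.9 ± 3.1 CPM), as was TNFSF14, a TNF family ligand (29.9 ± 12.1 against 3.39 ± 1.56 CPM). In Unstim CD86 was at 317 ± 72.3 CPM and TNFSF14 at 19.9 ± 8.44 CPM, both above LPS. Interferon-stimulated genes had 2 lower of 38, or none adjusted over the list alone and 7 with the donor block (median -0.78, adjusted p = 0.0161, and adjusted p = 0.849 with an estimated correlation). That call was lost without LPS replicate 4 or 5 or IC replicate 1 or 2 (adjusted p of 0.0839, 0.173, 0.102 and 0.103). CMPK2 was at 24.2 ± 13.3 CPM in IC and 118 ± 56.4 CPM in LPS. Toll-like receptors and adaptors passed at an adjusted p of 0.0483 (2 higher and 6 lower of 20, median -0.29) and not with an estimated correlation (adjusted p = 0.462 with an estimated correlation), the donor block (0.096) or library size only (0.06). That call was also lost without IC replicate 1 (0.0639) or 5 (0.128), LPS replicate 1 (0.0667), 2 (0.0501) or 4 (0.0723), Unstim replicate 4 (0.0526) or the 3 libraries of number 5 (0.0773). The classical monocyte list had 4 lower and none higher of 14, or 2 higher with the donor block (median -0.26, adjusted p = 0.00586, and adjusted p = 0.23 with an estimated correlation).

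Platelet markers had 9 higher and 1 lower of 12 in IC against LPS, or 10 higher adjusted over the list alone (median 1.51, adjusted p = 1.08e-05, and adjusted p = 0.241 with an estimated correlation). The mitochondrially encoded mRNAs had 10 of 13 higher (median 0.66, adjusted p = 1.01e-07, and adjusted p = 0.322 with an estimated correlation). T cell and neutrophil markers did not pass camera (adjusted p = 0.57 and 0.0702, and 0.889 and 0.507 with an estimated correlation). Each passed with the donor block at the preset correlation, at an adjusted p of 0.0494. Neutrophil markers also passed without IC replicate 2 (0.0407) or 4 (0.0213), LPS replicate 1 (0.0256) or 2 (0.0345) or the 3 libraries of number 5 (0.0397).

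**Figure D3:**
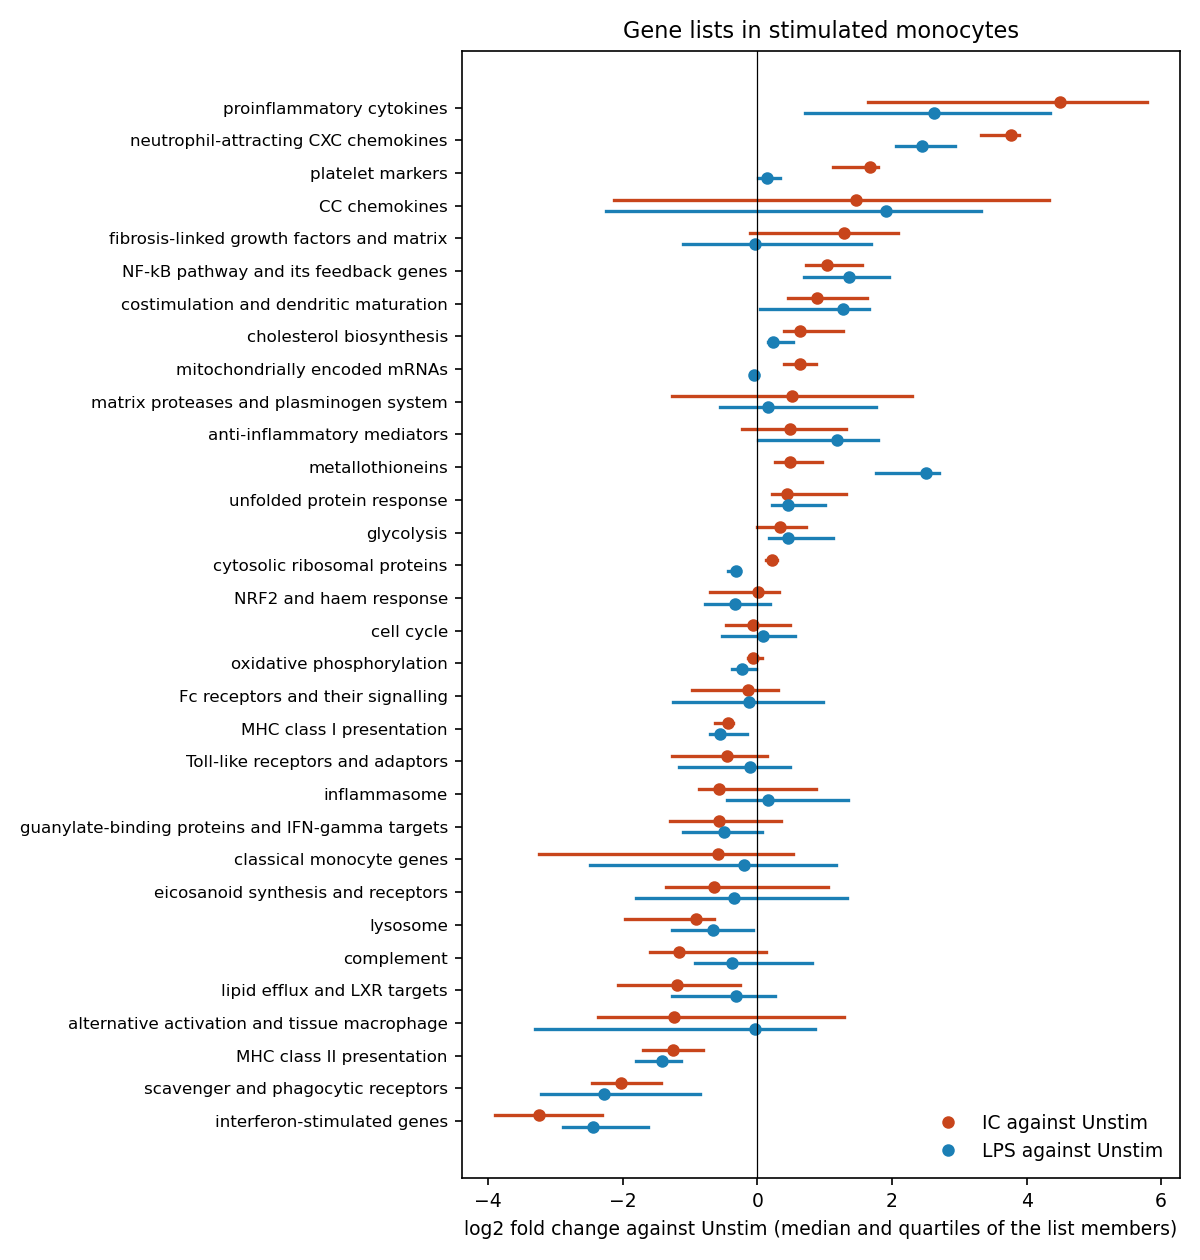
Median (points) and quartiles (lines) of the log2 fold changes of the tested members of 32 gene lists, for IC against Unstim (orange) and LPS against Unstim (blue). The medians of the interferon-stimulated genes lie at -3.25 and -2.44, those of the platelet markers at 1.68 and 0.14, and those of the metallothioneins at 0.48 and 2.50.

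Summed marker levels were compared for 9 other cell types and 2 signs of RNA quality by exact permutation, 2-sided, with 33 tests in the family, of which 14 passed. The smallest p that 5 against 5 libraries allow is 0.00794. Summed platelet markers were at 1030 ± 263 CPM in IC, 483 ± 95.1 CPM in LPS and 296 ± 66.3 CPM in Unstim. Both stimulated groups were above Unstim (exact p = 0.00794 and 0.0159, adjusted p = 0.0238 and 0.0374). In LPS the only member that passed edgeR's test was ITGB3, an integrin subunit, at 207 CPM against 33.9 CPM, looked at after the sums were seen. The platelet call in LPS against Unstim was lost without Unstim replicate 1, 2 or 4 or LPS replicate 2, 3 or 4 (adjusted p of 0.0561, 0.0524, 0.0561, 0.0561, 0.0561 and 0.0561). Summed mitochondrially encoded mRNAs were at 36300 ± 4060 CPM in IC, 24000 ± 3340 CPM in LPS and 24600 ± 3150 CPM in Unstim (IC against Unstim exact p = 0.00794, adjusted p = 0.0238). Summed T cell markers were at 1370 ± 337 CPM in IC, 2790 ± 584 CPM in LPS and 656 ± 210 CPM in Unstim, most of it from IL7R, the interleukin-7 receptor, which stood at 1300 ± 449, 2720 ± 687 and 582 ± 177 CPM. The T cell call in IC against Unstim (exact p = 0.0159, adjusted p = 0.0374, 4 of 5 donors) was lost without Unstim replicate 1, 2, 3 or 4 or IC replicate 1 or 3, at an adjusted p of 0.0561, or 0.0524 for Unstim replicate 2. Summed non-classical monocyte markers were at 695 ± 173 CPM in IC, 688 ± 148 CPM in LPS and 1570 ± 363 CPM in Unstim, and both stimulated groups were below Unstim (exact p = 0.00794, adjusted p = 0.0238). Most of that fall came from FCGR3A, at 111 ± 58.6, 69.9 ± 16.2 and 888 ± 217 CPM. Of the 9 members 4 were higher and 3 lower in IC (median 0.34, camera adjusted p = 0.842), and 3 were higher and 2 lower in LPS (median 0.49, adjusted p = 0.988). Summed neutrophil markers were lower in LPS (94.5 ± 51.4 CPM) than in Unstim (283 ± 55.8 CPM, exact p = 0.00794, adjusted p = 0.0238) and stood at 215 ± 104 CPM in IC. Summed plasmacytoid dendritic cell markers were at 45.6 ± 10.3 CPM in IC, 73.1 ± 32.9 CPM in LPS and 21.3 ± 8.31 CPM in Unstim (exact p = 0.00794, adjusted p = 0.0238, for each against Unstim). In LPS most of the sum was LILRA4, at 60.9 CPM. Of the 6 members 2 were higher in IC, or 4 with the donor block, and 1 in LPS, and the list did not pass camera (adjusted p = 0.45 and 0.825), while the permutation of list means called it in IC (0.0142) and not in LPS (0.0697). Summed erythroid markers were at 2.2 ± 0.768 CPM in IC and 0.784 ± 0.206 CPM in Unstim (exact p = 0.0159, adjusted p = 0.0374). Without Unstim replicate 1, 2 or 3 the erythroid call was lost (0.0561, 0.0524 and 0.0561), as were the plasmacytoid call in IC without IC replicate 1 or 2 and the neutrophil call in LPS without Unstim replicate 4 (0.0561 each). No comparison of summed B cell, NK cell or conventional dendritic cell markers, or of immediate early and heat shock genes, passed the test. The smallest adjusted p among these was 0.0873, for NK cell markers in LPS (139 ± 146 CPM) against Unstim (44.1 ± 61.6 CPM). This test does not pair the donors. The NK cell sum had the same direction in 5 of 5 donors in LPS against Unstim (log2 difference 1.95, SD of within-donor differences 0.5), IC against Unstim (1.14, SD 0.42) and IC against LPS (-0.81, SD 0.14). The sum of immediate early and heat shock genes was higher in 5 of 5 donors in IC (0.23, SD 0.15) and in LPS (0.40, SD 0.24) against Unstim. It stood at 4740 ± 459 CPM in IC, 5380 ± 810 in LPS and 4080 ± 756 in Unstim. IER3 alone stood at 2740 ± 338, 3100 ± 664 and 1390 ± 191 CPM, so it rose by more than the whole sum. Of the 14 members 9 were higher and 3 lower in IC, and 6 higher and 4 lower in LPS. The list did not pass camera (adjusted p = 0.127 and 0.568). Sign flips within 5 donors cannot give a p below 0.0625. Of 10 NK cell members 1 was higher in IC against Unstim, or 5 with the donor block, and 1 was lower in IC against LPS, or 6 with the block.

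**Figure D4:**
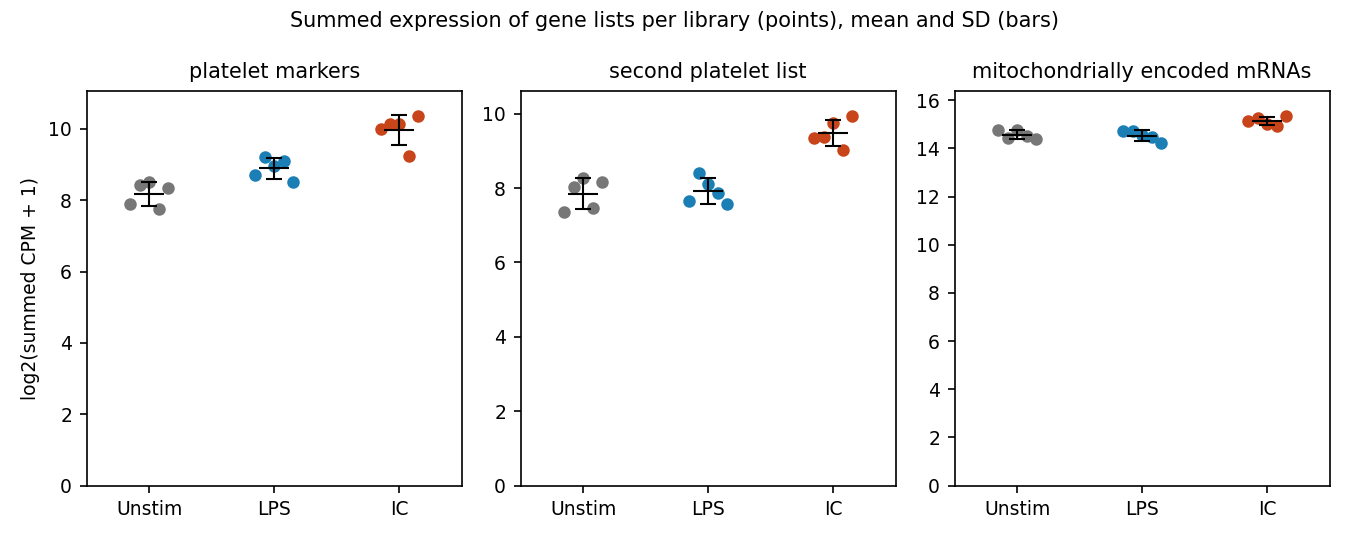
Summed expression per library of the platelet markers, a second list of platelet genes and the mitochondrially encoded mRNAs, with log2(summed CPM + 1) on the vertical axis from 0 and the groups on the horizontal axis (points, libraries; bars, mean and SD of 5). The platelet sum lies between 9.24 and 10.35 in IC, above the range of 7.75 to 8.5 in Unstim and of 8.5 to 9.21 in LPS.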

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

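The splits of libraries, the permutation tests of list means, the tests with library size only, the test of the interferon-stimulated genes within donors and the vehicle test were chosen only after the results had been seen, whereas the tests with the second platelet list and of platelet against mitochondrial sums were chosen before their values were.

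Other splits of the 10 libraries of a comparison into 5 and 5 were used to ask whether chance can be excluded for the counts called. Of 126 splits 100 were fitted, on these libraries alone. For genes the splits show only that the real grouping stood apart from other groupings of these libraries. The groups gave 6673 genes in IC against Unstim, 5448 in LPS against Unstim and 4015 in IC against LPS, and the highest other splits gave 0, 6 and 140, so 1 of 100 splits, the real one, reached the value each time. The other splits mix the groups, so their low counts give no rate of false calls among the genes called. For the number of lists that camera calls, these splits cannot decide. Every other split has unequal numbers of libraries of each group on its sides, so it keeps part of the group difference. The rest of that difference adds to the spread within each side, which also lowers the number of genes called. The groups gave 19, 14 and 17 lists, the highest other splits 23, 18 and 20, and 10, 15 and 14 of 100 splits gave as many. Of the splits that part all 5 pairs of a donor's libraries, as the groups do, 12, 10 and 12 were drawn. They gave 0 genes each and up to 22, 16 and 20 lists. For single lists the exact permutation of list means called 27, 22 and 14, of which camera called 16, 11 and 12 too. The other 1, 4 and 6 lists that camera called were not called by permutation, and with the donor block and an estimated correlation camera called 0 lists.

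Platelet markers were higher in IC than in Unstim, as a second list of platelet genes chosen to test this was, with a median log2 fold change of 1.62 (SE 0.15 over genes) and 19 of 21 genes higher. SEs over genes, here and below, treat the genes of a list as independent and do not measure the spread between donors. In LPS against Unstim the second list had 0 genes higher and 1 lower (median 0.14), and in IC against LPS 19 higher (median 1.48). Its most abundant members, chosen after values were seen, were NRGN (226 against 74.7 CPM), CAVIN2 (153 against 49.4), GNG11 (92.6 against 18.5) and CLU (61.8 against 17.8). With library size only the platelet marker median was 1.55 (SE 0.18 over genes), against 1.68 with TMM, so scaling does not account for it. RNA from platelets attached to monocytes on the IC plates may explain the rise, and a rise of these genes within the monocytes cannot be told apart from it in bulk RNA.

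Interferon-stimulated genes were lower in IC and LPS than in Unstim in 10 of 10 within-donor comparisons, with medians from -1.57 to -5.00 in IC and from -0.69 to -4.33 in LPS, so the fall does not rest on some donors only. With library size only the median in IC was -3.35 (SE 0.22 over genes), against -3.25 with TMM. The vehicle, named for the stimulated groups only, could have lowered these genes as well. The median between IC and LPS, which share the vehicle, was -0.78, and this cannot tell vehicle from stimulus. An effect of the stimuli on interferon signalling remains a hypothesis, and an effect of culture, not stated for Unstim, was not tested.

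Mitochondrially encoded mRNAs were higher in IC, with a median of 0.51 with library size only (SE 0.16 over genes) against 0.64 with TMM. Members differed, chosen here after values were seen: ND1 was at 1.37, and COX1 at -0.08 did not pass the test. Platelets carry these mRNAs, and over the 15 libraries the deviations of platelet and mitochondrial sums from the group means had r = 0.397 (permutation p = 0.161). That value cannot tell whether platelets brought them. A rise within the monocytes remains as possible.

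Dixon's ratio, the gap to the next library over the range of 5, passed its critical value of 0.71 in 20 of 269 groups of libraries, and 13.4 are expected by chance at 1 in 20. The highest library in summed NK cell markers stood apart in Unstim (0.823), LPS (0.799) and IC (0.836). In Unstim the lowest library stood apart for ALOX5 (0.742) and PTGS1 (0.807) and the highest for TGFBI (0.738). In LPS the highest stood apart for CCL23 (0.867), CCL7 (0.762), CCL8 (0.994), EGR2 (0.771) and RNASE1 (0.845), and the lowest for FCGR3A (0.714), TIMP3 (0.745) and TNF (0.714). In IC the lowest stood apart for CTSD (0.776), CXCL6 (0.747), IL7R (0.732), PPBP (0.824), SLAMF1 (0.804) and TNIP3 (0.895).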

How the results depend on the processing

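Of 135 gene results over 97 genes, 128 had the same call in every alternative, and of 3645 recomputed values 8 lost the call and 0 reversed. These genes were named mainly for large fold changes in these same data, so steady calls are partly built in and do not stand for all genes. CCL8 lost its call with limma-voom in IC against Unstim (adjusted p = 0.0635) and LPS against Unstim (0.0786), as CCL7 did in IC against LPS (0.0694). At a threshold of 0.01 MT1M (0.0187), CASP5 (0.0157), CMPK2 (0.0182) and IL7R (0.0143) were not called in IC against LPS, and MT1M was not without the 3 libraries of number 5 (0.0552). In IC against LPS the counts moved to 1211 higher and 1077 lower genes at 0.01, and to 1499 higher and 1731 lower genes without LPS replicate 2. Without IC replicate 1 or LPS replicate 1, 1551 and 1553 genes were higher and 1751 and 1749 lower. Which direction held more genes in IC against LPS thus depended on the fit. Leaving out 1 library gave 2881 to 3750 higher and 2929 to 3818 lower genes in IC against Unstim, 2533 to 2990 and 2769 to 3258 in LPS against Unstim, and 1499 to 2398 and 1731 to 2221 in IC against LPS. The donor block gave 4508 and 4300, 3593 and 3985, and 3262 and 2879 genes, and it lost 4 and gained 3 of 123 list calls. It changed no call among the 135 gene results. Other genes named by the rule did change. NKG7 gained a call in LPS against Unstim (edgeR adjusted p = 0.161, and 0.000182 with the block), and IL1R2 lost one in IC against LPS (0.0341, and 0.0616 with the block). The 17, 15 and 18 lists called became 5, 0 and 0 with an estimated correlation and 0, 0 and 0 with the block as well. In IC against Unstim fry called 28 lists, 32 with the block, and permutation 27. In LPS against Unstim fry called 25 and 29 with the block. The r of the responses was 0.783 to 0.81 without 1 library and 0.667 with the controls split, where 1301 genes were higher in both. The split fits kept 15786 genes and fewer controls per comparison. Sign flips within donors called 0 of 33 summed markers, since 5 donors allow no p below 0.0625. The 594 recomputed marker sums held 558 same, 32 weaker and 4 stronger calls and 0 reversed. The choices and most alternatives were fixed before the data were examined, and the fits without number 5, with IDs without a symbol, with fry or an estimated correlation under the block and with permutation of list means were added after the data had been seen. A planned change of pseudocount for normalized values was not run, as the files hold counts. The planned change for summed markers, to 0.1 CPM, was run and is among the recomputed marker sums. The cause of these differences was not tested.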

Other observations

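Genes of the unfolded protein response had 7 higher and 2 lower of 16 in IC against Unstim (median 0.44, camera adjusted p = 0.00929, and adjusted p = 0.302 with an estimated correlation). TRIB3, a kinase-like protein induced by this response, rose from 1.12 ± 0.559 to 20.6 ± 9.55 CPM (log2 fold change 4.19 ± 0.41, edgeR adjusted p = 1.67e-06) in 5 of 5 donors. In LPS against Unstim the list had 6 higher and 2 lower, or 8 higher adjusted over the list alone, and did not pass camera (adjusted p = 0.141), while the permutation of list means called it (0.0163). Glycolysis genes had 9 higher and 2 lower of 22 in LPS against Unstim (median 0.45, adjusted p = 0.0205, and adjusted p = 0.767 with an estimated correlation), a call lost without LPS replicate 2 (adjusted p = 0.0932). PFKFB3, a regulator of glycolysis, rose from 1100 ± 244 to 4400 ± 960 CPM. In IC against Unstim the glycolysis list had 8 higher and 4 lower and did not pass (adjusted p = 0.267).

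MHC class I presentation had 6 lower of 15 in IC against Unstim, or 5 adjusted over the list alone and 12 with the donor block (median -0.44, adjusted p = 0.0382, and adjusted p = 0.595 with an estimated correlation). That call was lost without Unstim replicate 1 or 5 or IC replicate 2 or 3 (adjusted p of 0.052, 0.105, 0.0635 and 0.0535). Oxidative phosphorylation had 6 higher and 1 lower of 31 in IC against LPS, or 5 higher adjusted over the list alone and 12 with the donor block (median 0.15, adjusted p = 0.0242, and adjusted p = 0.811 with an estimated correlation), a call lost without IC replicate 1 (0.0967) or 3 (0.0666) or LPS replicate 1 (0.066), 2 (0.0628), 3 (0.0544) or 5 (0.0678). Complement (2 higher and 10 lower of 17, adjusted p = 0.127) and Fc receptors and their signalling (3 higher and 7 lower of 20, adjusted p = 0.16) did not pass camera in IC against Unstim, while the permutation of list means called both (0.0142 each). Of the tests in these 2 paragraphs, only the permutation was chosen after the result was seen.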
